A study of Mus musculus with 2 samples.

How the data were processed

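RNA from thymus of 6-month-old mice carrying a Pla2g10 transgene and of littermates without it was compared on 2 two-colour Agilent arrays. Per the labels, RNA of 4 mice was pooled for each genotype, labelling started from 500 ng of RNA, and the strain background was C57BL/6. On array 1 the transgenic pool carried Cy5 (red) and the control pool Cy3 (green), and on array 2 the dyes were exchanged, per the labels. The labels call the arrays replicates 1 and 2 and do not say whether they hold separate pools. They were treated as a technical dye swap of the same pools, so each genotype counted as 1 replicate and no test across animals was made.

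The deposited scanner files hold, for each spot and channel, the mean and local background intensity on a linear scale, without background correction. They were written by Feature Extraction 9.5.1.1, per the file headers. That software also gave a processed intensity, made with spatial detrending, a lowess dye normalization and surrogate signals for dim spots, per the file headers. The deposited LogRatio column is log10 of red over green processed signal, and a p-value of each log ratio comes from the software's error model for that array, per the file headers. The deposited series table of log10 values matched log10 of red over green processed signal at every spot within 5e-10. It was neither turned for the dye swap nor centred, and its medians were -0.113 and -0.101 on arrays 1 and 2. Any treatment of the RNA or arrays beyond these statements is not given in the sources used here.

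Each array held 41534 spots for transcripts and 2256 control spots. Mean signals were corrected with the median local background by normexp with an offset of 50, then normalized by loess within each array, with control spots and outlier spots at weight 0 in the loess (limma 3.58.1 in R 4.3.3). Spots marked as non-uniformity or population outliers were left out, 46 on array 1 and 37 on array 2, and saturated spots were kept. Spots of a probe were averaged and array 2 was multiplied by -1, so that every log2 ratio reads transgenic over control. Over 11333 spots well above background in all 4 channels, the red over green ratios of the 2 arrays correlated at -0.269 before turning, the sign a dye swap gives.

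A probe was tested if it was well above background in the channel of 1 genotype on both arrays, which 12236 of 41174 probes were. Probe names came from a RefSeq table of assembly GRCm38.p6. The accession named 23366 probes, the symbol 6739 and a synonym 2918, and 8151 kept the name of the array design. The brightest probe stood for each gene, leaving 9398 genes, 8404 of them with a symbol of the table. Probe positions are on mm8, as the file headers state. No annotation of that build was used, so the exon or UTR a probe lies in is not given.

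A gene was called at least 2-fold different if its mean log2 ratio was at least 1 in size and at least 0.5 on each array with the same sign. The same rule was applied to the dye contrast, the difference between the arrays divided by 2, as a technical level. A gene not well above background in 1 genotype on both arrays has only a bound there, written as "at least N-fold". It sets the bright channel's mean against the higher of the dim probe's level and the lowest level of probes well above background, after loess and Aquantile scaling.

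Before the data were examined, 40 gene lists were fixed. For lists with at least 5 measured genes, the median log2 ratio was set against 10000 random lists of the same size matched on intensity in 20 bins. A list stood apart if its median lay below the 2.5th or above the 97.5th percentile and had 1 sign on both arrays. Two-sided permutation p-values were adjusted over the 34 such lists by the Benjamini-Hochberg method. They describe these pools, since genes are not replicates. Genes named in the text were Pla2g10, the 15 highest and 15 lowest called genes without clone, gene model or receptor segment names, and up to 4 members per list. These members were the called ones or, in lists with none, the measured ones with the largest absolute log2 ratios. Some genes that this rule takes are not reported here. Probes of 1 gene that differ in sign are stated. Other list members, and genes named for a count or singled out, were chosen after their values were seen.

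The log2 ratios carry an offset of 50 added to each channel, which shrinks them at low signal. In tested genes the mean signal above local background had a median of 95.9, and 27.0% of them had under 50. The procedure was tested on simulated dye-swapped arrays built on all probes with a value on both arrays. At each fold 50 of the 12236 tested probes were changed, and calls were counted among the tested probes. The rule called 6% of probes changed 2-fold, 46% of those changed 3-fold and 70% of those changed 4-fold, and no unchanged probe. With an offset of 0 it called 50% at 2-fold and 100% at 3-fold. All simulated changes had the right sign. The simulation gave all probes noise of the same size and a dye bias that depended only on intensity. Its lack of unchanged calls and its right signs therefore do not cover gene-specific dye bias or noisier probes. In simulated lists of 10 genes drawn from the 9398 genes, 2% of 200 lists with no added change stood apart, 60.5% with 0.1 added and 99% with 0.2 added. These lists were random draws, so the 2% does not apply to lists whose genes move together.

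Alternatives were another offset, no background correction, median centring, Aquantile, the software's own log ratios, the series table, other filters, saturated spots left out, the mean over probes, each array alone, other size rules, and limma's moderated test with the arrays as separate measurements. Putting dim genes at their bound was added after the data were seen. With 1 replicate per genotype, the number of arrays limits the precision. Calculations outside R used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.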

Results

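Pla2g10 encodes group X secreted phospholipase A2, an enzyme that releases fatty acids and lysophospholipids from phospholipids. Gene expression was measured in the thymus, the organ in which T cells mature, of 6-month-old mice with a Pla2g10 transgene, overexpressing per the labels, and of littermate controls. RNA from 4 mice was pooled per genotype, taken here as 1 pool each, and both genotypes were hybridised together on 2 arrays with exchanged dyes. The comparison asks which transcripts differ between the transgenic and the control thymus. On array 1, 34.1% of spots were well above background in the transgenic channel and 29.0% in the control channel. On array 2 these shares were 28.5% and 33.2%, so the red channel had the higher share on both arrays. Values are log2 ratios of transgenic over control, as the mean of both arrays ± the SD between them (n = 2 arrays of 1 pair of pools). With the same 1 pool per genotype taken for both arrays, that SD is technical, and no difference has a replicate check across animals.

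Pla2g10 itself was not measurable. Its only probe (A_51_P380451, transcript NM_011987, mm8 chromosome 16, 13628751 to 13628810) was well above background in 0 of 4 channels. The transgenic channels read 35.3 and 43.0 and the control channels 45.1 and 39.5 units on arrays 1 and 2, over local backgrounds of 34 to 36. The log2 ratio was -0.04 ± 0.03. The labels do not say which part of the gene the transgene carries, so this probe does not check them.

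In the transgenic thymus, transcripts of fat cells, haemoglobin, neutrophils, medullary epithelium and glucocorticoid response rose, and markers of immature thymocytes fell. Of 9398 genes, 3 were called at least 2-fold higher and 0 at least 2-fold lower. Cfd, which encodes the complement protease adipsin made by adipocytes, reached 1.61 ± 0.01, and 3.26 with an offset of 0. Its probe was not well above background in the control pool on either array, so the transgenic level was at least 2.97-fold higher. Hbb-bt, an adult beta-globin gene, reached 1.18 ± 0.27, and all 4 of its probes were higher, between 0.86 and 1.18; near-identical globin genes can share these probes. Cirbp, a cold-inducible RNA-binding protein gene, reached 1.07 ± 0.19. With median centring in place of loess, Hbb-bt and Cirbp lost their calls, as array 2 then read 0.39 and 0.13. The Cfd, Hbb-bt and Cirbp probes lie on mm8 at chromosome 10, 79295686 to 79295745, chromosome 7, 103687307 to 103687366, and chromosome 10, 79574658 to 79574717.

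The dye contrast gave 0 genes under the same rule. Across genes, the turned ratios of the 2 arrays correlated with r = 0.311 and Spearman rho = 0.240, and genes are not independent replicates. At least 0.5 on each array, 27 genes were higher and 5 lower, against 0 in the dye contrast. Probes well above background in only 1 dye on both arrays were not tested. A dye effect could give such probes, so these counts of 0 may understate the technical level. The count of genes at least 2-fold different, 3 higher and 0 lower, depends on the offset: with an offset of 0 it was 26 higher and 1 lower. Without background correction it was 4 higher and 0 lower. With the software's own log ratios, which also differ in detrending, dye normalization and the signals of dim spots, it was 32 higher and 5 lower. limma's moderated test with the arrays as separate measurements, which covers only the spread between arrays, gave 82 genes higher and 42 lower at adjusted p under 0.05.

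**Figure D1:**
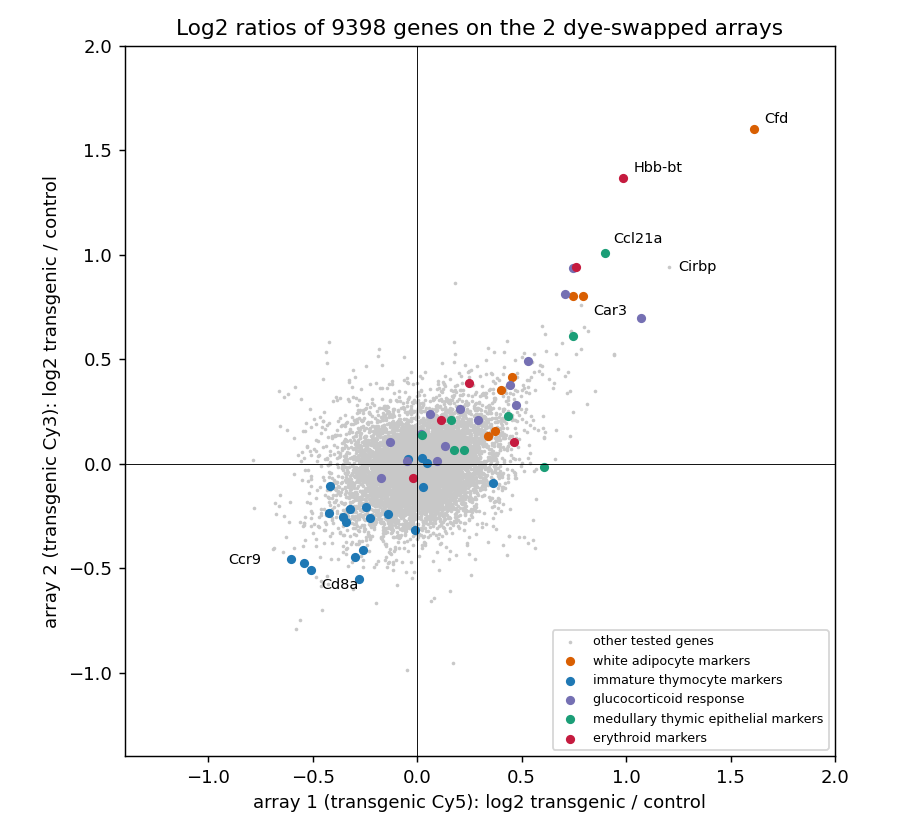
Log2 ratio of transgenic over control on array 1 (x axis) and array 2 (y axis) for each of the 9398 tested genes, with the members of 5 gene lists coloured. Cfd is the highest gene on each array, and Cd8a and Ccr9 lie below 0 on both.

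Immature thymocyte markers fell, with a median of -0.27 over 20 measured genes, 17 of them below 0. The median was -0.27 on array 1 and -0.25 on array 2, below all 10000 matched random lists. Ccr9, the receptor for the thymic chemokine CCL25, was at -0.53 ± 0.10. Cd8a, a co-receptor chain, was at -0.51 ± 0.00. Dntt, the terminal transferase of receptor gene rearrangement, was at -0.41 ± 0.20. Rag1 was at -0.31 ± 0.04 and Cd4 at 0.02 ± 0.00. Cell cycle genes fell slightly, with a median of -0.08 over 37 genes, 26 of them below 0, including the mitotic kinase genes Plk1 (-0.38 ± 0.09), Cdk1 (-0.29 ± 0.08) and Aurka (-0.24 ± 0.00). On array 1 alone the cell cycle median of -0.06 did not stand apart.

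T cell receptor signalling components did not stand apart, with a median of -0.06 over 27 genes at percentile 4.80 of the matched random lists. They stood apart as lower with an offset of 0 (-0.096), with the software's log ratios and the series table (-0.093), and on array 2 alone (-0.11). Within them Egr2 was at -0.31 ± 0.00 and Tox at 0.28 ± 0.35, the higher of its 2 probes, with the other at 0.018. Early progenitor markers stood apart at a median of 0.13, with 6 of 6 above 0 and Notch3 highest at 0.24 ± 0.03 (adjusted permutation p = 0.0690). Mature T cell markers stood apart at a median of 0.08, with 12 of 18 above 0 (adjusted permutation p = 0.0902). Ms4a4b was at 0.67 ± 0.17, the highest of its 4 probes, with the lowest at 0.25. Ccr7, the receptor that guides mature thymocytes to the medulla, was at 0.45 ± 0.15. Klf2 was at -0.54 ± 0.20, but its other probe read 0.59. Neither list stood apart with the software's log ratios, at 0.21 (early progenitor) and 0.11 (mature T cell). With no filter on dim probes both did, at 0.070 and 0.056. Early progenitor markers did not on array 1 alone, at 0.15, and mature T cell markers did so on neither array alone. Regulatory T cell markers had a median of 0.07 over 6 genes and did not stand apart, but did at 0.19 with an offset of 0 and at 0.21 with the software's log ratios and the series table.

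Glucocorticoid response genes rose, with a median of 0.23 and 12 of 15 above 0. The median was 0.15 with no filter on dim probes and 0.48 with the software's log ratios, and the list still stood apart. Mt2, a metallothionein gene, was at 0.89 ± 0.26. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, was at 0.84 ± 0.13, the highest of its 3 probes, with the lowest at 0.38. Ddit4, a stress-induced inhibitor of mTOR signalling, was at 0.76 ± 0.07. Fkbp5, a co-chaperone of the glucocorticoid receptor, was at 0.51 ± 0.03, the highest of its 3 probes, with the lowest at 0.011. Klf13 was at -0.12 ± 0.07. Apoptosis genes had a median of -0.06 over 20, but 0.066 on array 1 and 0.016 on array 2. The median was -0.04 over 14 immediate early genes, -0.05 over 17 heat shock and unfolded protein response genes and 0.01 over 20 oxidative stress genes. None of these 4 lists stood apart.

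White adipocyte markers rose, with a median of 0.44 and 7 of 7 above 0, and 7 of the 20 listed genes were measured. The median was 0.099 with no filter on dim probes and 0.85 with the software's log ratios, and the list still stood apart. Beside Cfd, the carbonic anhydrase gene Car3 was at 0.80 ± 0.00, the fatty acid carrier gene Fabp4 at 0.78 ± 0.04, the lipid droplet gene Cidec at 0.44 ± 0.03 and the lipoprotein lipase gene Lpl at 0.38 ± 0.03. Car3 and Cidec were not well above background in the control pool, with bounds of at least 1.58-fold and at least 1.23-fold higher. With the 3 dim genes at their bounds the median was 0.38. Only 3 brown adipocyte markers were measured, too few to set against random lists. They were Cidea at 0.73 ± 0.13 (at least 1.59-fold higher), Cox8b at 0.50 ± 0.08 (at least 1.23-fold higher) and Cox7a1 at 0.20 ± 0.01, with a median of 0.30 at the bounds.

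Haemoglobin and neutrophil granule transcripts also rose. Erythroid markers had a median of 0.30, with 5 of 6 above 0, and 6 of 20 listed genes were measured. Among them Hba-a1 was at 0.85 ± 0.13, the haem synthesis gene Alas2 at 0.32 ± 0.10 and the transferrin receptor gene Tfrc at -0.05 ± 0.03. A list of 14 further red-cell and platelet genes, added after the data were examined, had a median of 0.0025 with 7 of 14 above 0, at percentile 56.9. Neutrophil granule markers had a median of 0.35, with 6 of 6 above 0 and 6 of 23 listed genes measured, and 0.23 on array 2 alone. With no filter on dim probes the medians were 0.039 (erythroid) and 0.041 (neutrophil), and both lists still stood apart, as they did at 0.69 and 0.68 with the software's log ratios. S100a9 was at 0.62 ± 0.01, Chil3 at 0.38 ± 0.02, S100a8 at 0.37 ± 0.34 and Camp at 0.34 ± 0.04. Macrophage markers did not stand apart, with a median of -0.0024 over 16 genes (0.077 on array 1 and 0.025 on array 2), C1qb at -0.18 ± 0.15 and Apoe at 0.32 ± 0.08. Nor did B cell (0.08 over 6), plasma cell (0.02 over 5), natural killer (0.09 over 5) or endothelial markers (0.05 over 5), though natural killer markers did at 0.24 with an offset of 0 and at 0.33 with the software's log ratios and the series table. The B cell list holds Rag1 (-0.31 ± 0.04), also listed as an immature thymocyte marker. Without Rag1 the B cell median was 0.13 over 5 genes, which was not set against random lists.

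Medullary thymic epithelial markers rose, with a median of 0.24 and 8 of 8 above 0. The median was 0.090 with no filter on dim probes and 0.42 with the software's log ratios, and the list still stood apart. Ccl21a, a chemokine gene that attracts CCR7-bearing thymocytes, was at 0.95 ± 0.08, and close copies of it can share the probe. The keratin genes Krt5 and Krt14 were at 0.68 ± 0.10 and 0.33 ± 0.14, and Ccl19 at 0.29 ± 0.44, with array 2 at -0.02. Cortical epithelial markers stood apart at a median of 0.10 with 10 of 14 above 0 (adjusted permutation p = 0.0502), but did so neither on 1 array alone (0.062 and 0.11 on arrays 1 and 2) nor without the filter on dim probes (0.032). Epidermal and keratin genes rose with a median of 0.14 and 8 of 10 above 0, led by Trp63 at 0.54 ± 0.27. On array 2 alone, at 0.10, or without that filter, at 0.028, they did not stand apart.

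Dendritic cell and MHC class II genes rose, with a median of 0.14 and 13 of 13 above 0 in the mean of both arrays. Only 9 of the 13 had the same sign on both arrays, and the median was 0.12 on array 1 and 0.20 on array 2. Among them H2-Eb1 was at 0.30 ± 0.26. H2-Ab1 was at 0.30 ± 0.12, the highest of its 4 probes, with the lowest at 0.049. Fibroblast and matrix genes rose with a median of 0.16 and 9 of 10 above 0, including the proteoglycan gene Dcn at 0.52 ± 0.04 and Mgp at 0.52 ± 0.19. With no filter on dim probes the medians were 0.069 (dendritic cell) and 0.042 (fibroblast), and with the software's log ratios 0.29 and 0.23, and both lists still stood apart. Type I interferon response genes rose with a median of 0.09 and 16 of 18 above 0, Ifit3 being at 0.30 ± 0.11. Ribosomal protein genes rose with a median of 0.12 and 33 of 38 above 0. On array 1 alone neither the interferon median of 0.10 nor the ribosomal median of 0.04 stood apart, while both lists did on array 2 alone, the ribosomal one at 0.19. With the software's log ratios the interferon median was 0.19. Smooth and skeletal muscle markers had a median of -0.05 over 7, complement genes -0.0016 over 7 and oxidative phosphorylation genes -0.03 over 33, and did not stand apart, except muscle markers on array 1 alone at -0.15 and complement genes with no filter on dim probes at 0.037.

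Genes of the pathways downstream of phospholipase A2 did not stand apart on both arrays together. The phospholipase A2 family had a median of 0.07 over 7 measured of 24 listed genes, Pnpla8 being at 0.17 ± 0.32 and Pafah2 at -0.12 ± 0.04. Eicosanoid synthesis and receptor genes had a median of 0.05 over 10 measured of 36 listed genes, with 5 above 0. They ran from Tbxa2r, the thromboxane receptor gene, at -0.28 ± 0.32 to Cbr2 at 0.36 ± 0.09. Lysophospholipid enzymes and receptors had a median of 0.02 over 9 measured of 22 listed genes. Among them the lysophosphatidic acid receptor gene Lpar6 was at -0.51 ± 0.04, and Lpcat2 at 0.36 ± 0.16. Fatty acid oxidation genes had a median of 0.03 over 14, and fatty acid and cholesterol synthesis genes 0.02 over 18 (-0.00019 on array 1 and -0.038 on array 2). The first 3 lists each stood apart as higher on 1 array alone, the phospholipase A2 family at 0.10 and the lysophospholipid list at 0.14 on array 2, and the eicosanoid list at 0.13 on array 1. Most listed genes of these 3 lists were not measured, so the medians cover only a part of each list.

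**Figure D2:**
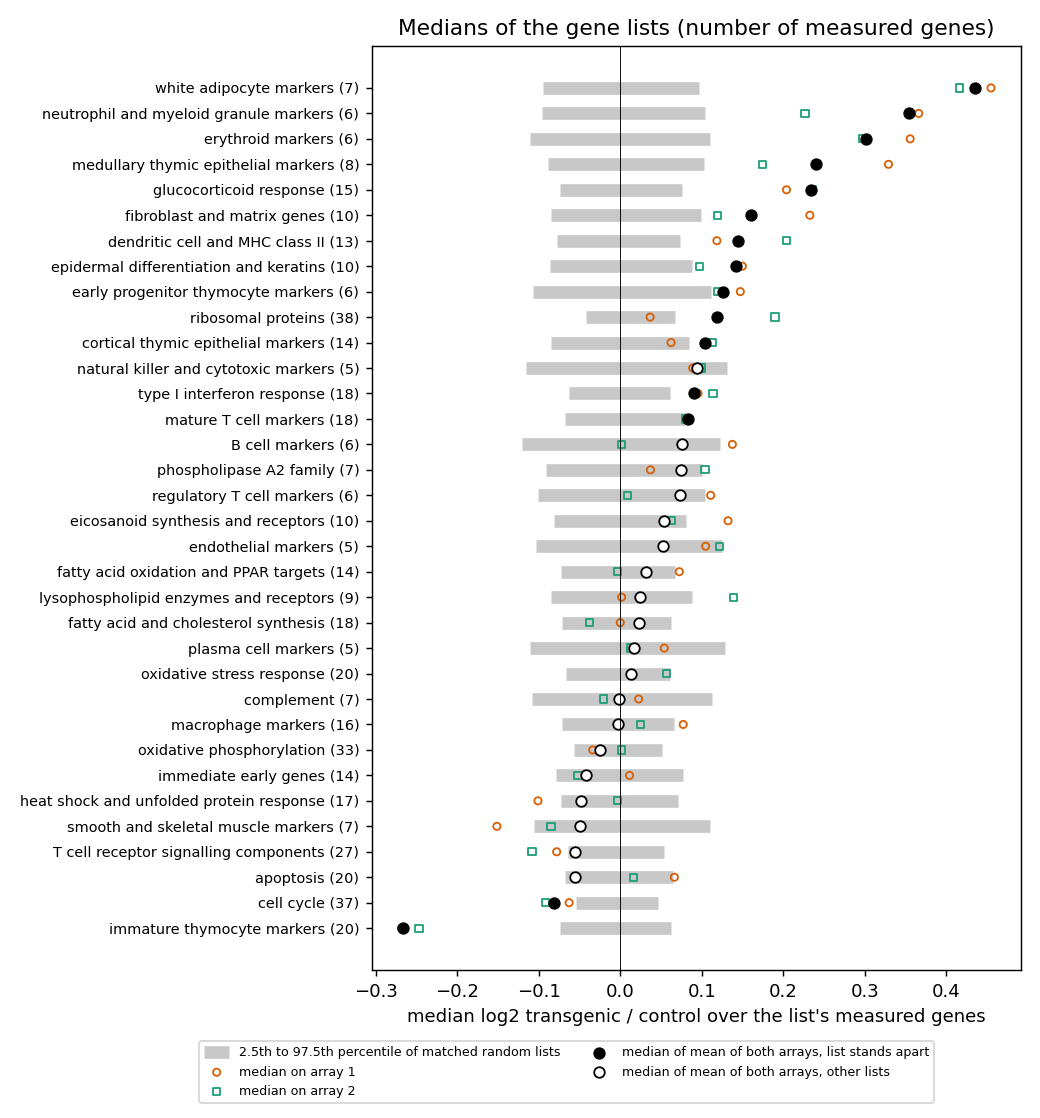
Median log2 ratio of transgenic over control (x axis) of each of the 34 lists with at least 5 measured genes (y axis), on each array and for the mean of both arrays, with a grey bar for the range of 10000 matched random lists that a list has to leave to stand apart. White adipocyte markers are highest at 0.44 and immature thymocyte markers lowest at -0.27.

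**Figure D3:**
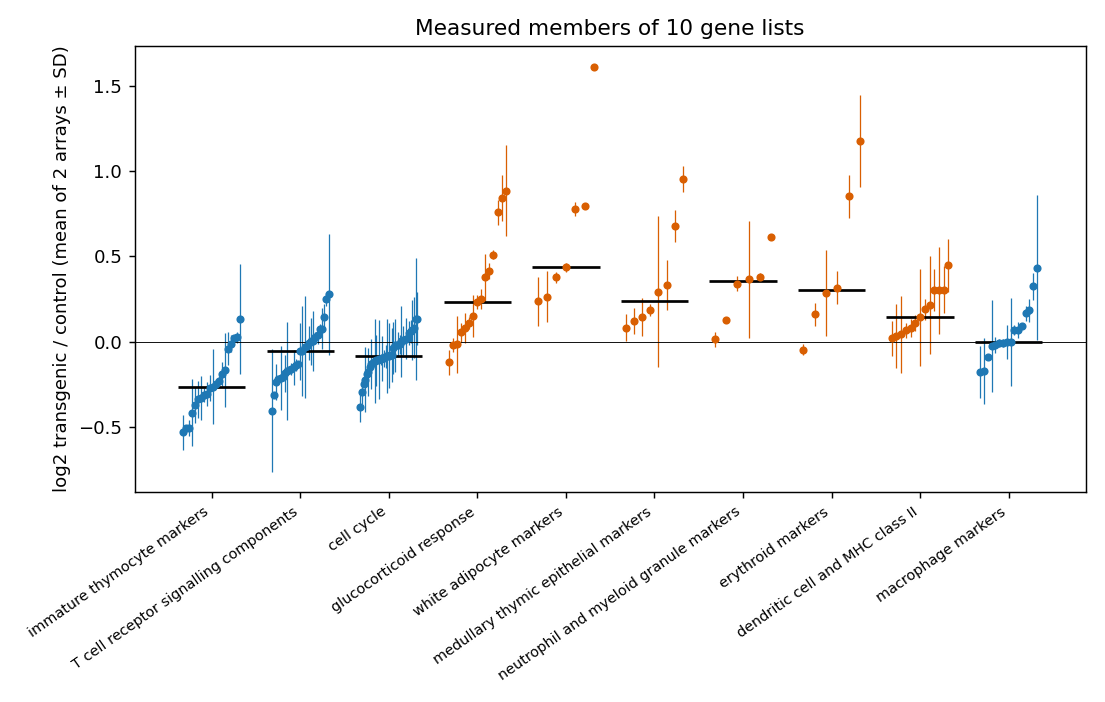
Log2 ratio of transgenic over control (y axis; mean of 2 arrays, bars are the SD between them) of each measured member of 10 gene lists (x axis), with the list median as a black line. In white adipocyte markers 7 of 7 members lie above 0, and in immature thymocyte markers 17 of 20 lie below 0.

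Of the 34 lists, 15 stood apart, 13 higher and 2 lower, and 12 had an adjusted permutation p under 0.05. With median centring in place of loess, where the turned arrays correlated at -0.454, 1 list stood apart, the white adipocyte markers. Of lists with fewer than 5 measured genes, beside the brown adipocyte one, tissue-restricted antigens had 1 (Reg3g at 0.44 ± 0.14). Inflammatory cytokines and chemokines had 4 with a median of 0.05, mast cell and eosinophil markers 2 with a median of 0.11, and parathyroid and thyroid markers 2 with a median of 0.08.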

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

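Of the tests in this part, those on the clock genes and on the further adipocyte, glucocorticoid-induced and red-cell and platelet genes were chosen before their values were looked up, and the others after the results were seen.

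The spike-in control spots, which no comparison uses, gave a signal in both channels. Their observed log ratios followed the expected ones with a slope of 0.919 on array 1 and 0.915 on array 2, as the scanner software recorded. Median spike-in signals on array 1 were 779 (green) and 1200 (red), against 44.7 and 37.5 at negative control spots.

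Fat-cell transcripts were higher in the transgenic pool. Gene-specific dye bias would turn their sign between the arrays, but with no filter on dim probes 20 of 29 white and brown adipocyte markers were higher on both (more than in any matched random list), and of the markers well above background in both genotypes 4 of 4 were. Adipose tissue in or on the pooled thymi may account for them, though a further list of 10 adipocyte genes had a median of 0.056, at percentile 92.3 of matched random lists, which decides nothing. Of the abundant fat transcripts, Adipoq read 0.39 with 1 of 4 channels well above background, and the Plin1, Retn and Lep probes were well above background in 0 channels. Whether fat was within or around the organ cannot be told apart from a transgene effect with 1 pool per genotype, and the transgene effect was not tested.

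Immature thymocyte markers were lower in the transgenic pool. A lower share of these cells alone would raise the markers of other cell types alike. The medians of 12 other types ran from -0.05 to 0.44, wider than with genes permuted among lists (permutation p = 0.0128). The permutation did not match genes on intensity, and the offset shrinks dim genes more, so an equal rise could still give unequal medians. The highest median was that of white adipocyte markers, where 3 of 7 genes were not well above background in the control pool. This test therefore cannot exclude a lower share alone. Dilution of all thymocyte RNA would lower T cell receptor signalling genes as much, if these came from the same cells. The median of immature markers minus theirs was -0.21 (permutation p = 0.00101). It was -0.14 on array 2 alone (permutation p = 0.00904) and -0.19 on array 1 alone (permutation p = 0.0499). The signalling genes are not limited to immature thymocytes, and the permutation did not match genes on intensity. Dilution may therefore still account for a part of the fall. Glucocorticoid exposure, from stress or handling or as a consequence of the transgene, may contribute. A list of 10 further glucocorticoid-induced genes had a median of 0.13 with 7 above 0, at percentile 99.7 of matched random lists. One of them, Klf15, was not well above background in the control pool. With Txnip, Arrdc3 and Rgcc, whose values had been seen, the median was 0.14 over 13. The random lists were matched on intensity only, and 13 of the 15 lists that stood apart were higher. A lower share of immature thymocytes could raise these genes too, so this test cannot separate such a share from glucocorticoid exposure. A different time of day at sampling stays open, with a median absolute log2 ratio of 0.14 over 8 clock genes at percentile 95.3, and the genotype effect itself was not tested.

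Haemoglobin transcripts were higher in the transgenic pool. Whether they come from more blood in the transgenic pool cannot be told apart from other sources, as 14 further red-cell and platelet genes had a median of 0.0025 with 7 of 14 above 0, at percentile 56.9 of matched random lists. The 4 measured erythroid markers other than globins, too few to test, read 0.32 (Alas2), 0.28 (Bpgm), 0.16 (Fech) and -0.05 (Tfrc). A transgene effect was not tested.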

How the results depend on the processing

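The tests here were planned before the data were examined, except placing dim genes at their bound, chosen after seeing them, which turned no list median. No list that stood apart and no called gene changed sign where an alternative gave it a value. With genes well above background in both genotypes, the white adipocyte list and Cfd have none. All 3 called genes kept their call with an offset of 0, no background correction, Aquantile, the software's log ratios and the mean over probes. On array 1 alone Hbb-bt lost its call at 0.99, and on array 2 alone Cirbp did at 0.94. Pla2g10, not well above background, read -0.61 with an offset of 0, 0 with the software's log ratio and -0.089 in the series table. The genes at least 2-fold higher and lower numbered 26 and 1 with an offset of 0, 4 and 0 without background correction, and 32 and 5 with both the software's log ratios and the series table, which also differ in detrending, dye normalization and the signals of dim spots. With at least 1 required on each array 1 gene was higher.

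With median centring, 1 gene was higher and 1 list stood apart. Cfd kept its call at 1.61 ± 0.47. Hbb-bt, at 1.13 ± 1.04 after 1.18 ± 0.27, and Cirbp, at 1.02 ± 1.26 after 1.07 ± 0.19, lost theirs because array 2 read 0.39 and 0.13, under the 0.5 required on each array. The turned arrays then correlated at -0.454, since the intensity trend of the dyes remained on each array. The medians were -0.32 (immature thymocyte), 0.091 (early progenitor), 0.053 (mature T cell), -0.12 (cell cycle), 0.22 (glucocorticoid), 0.070 (cortical epithelial), 0.21 (medullary epithelial), 0.13 (epidermal), 0.13 (dendritic cell), 0.33 (neutrophil), 0.27 (erythroid), 0.11 (fibroblast), 0.088 (interferon) and 0.083 (ribosomal).

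The cause of the other losses was not tested. Early progenitor and mature T cell markers, at 0.21 and 0.11, no longer stood apart with the software's log ratios or the series table. Cortical epithelial and epidermal genes, at 0.032 and 0.028, did not with no filter on dim probes, nor mature T cell markers, at 0.085, with genes well above background in both genotypes. With 1 array left out, the medians ranged from 0.12 to 0.15 (early progenitor), 0.081 to 0.082 (mature T cell), -0.092 to -0.063 (cell cycle), 0.062 to 0.11 (cortical epithelial), 0.10 to 0.15 (epidermal), 0.095 to 0.11 (interferon) and 0.036 to 0.19 (ribosomal).

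Other lists stood apart only under an alternative. Regulatory T cell (0.19), T cell receptor signalling (-0.096) and natural killer (0.24) lists did so with an offset of 0, and the same 3 with the software's log ratios and the series table, at 0.21, -0.093 and 0.33. On array 2 alone 3 did, the phospholipase A2 family (0.10), lysophospholipid (0.14) and T cell receptor signalling (-0.11) lists. On array 1 alone 2 did, the eicosanoid (0.13) and muscle (-0.15) lists, and with no filter on dim probes 1, complement (0.037).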

Other observations

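Cd8a, Cirbp, Cfd, C1qb, Xist, Ddx3y and Eif2s3y were named by the rules fixed in advance. The other genes in this part were chosen after their values were seen, and no test was planned for them.

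Under both the offset of 0 and the software's log ratios, 26 genes were at least 2-fold higher and 1 lower. Many were dim and of the same kinds as the lists above. They included the glycerol phosphate dehydrogenase gene Gpd1, abundant in fat (0.73 ± 0.30 with the offset of 50, 1.82 with an offset of 0), the growth factor binding protein gene Igfbp5 (0.58 ± 0.20 and 1.34), the matrix gene Tgfbi (0.53 ± 0.09 and 1.06) and the annexin gene Anxa1 (0.47 ± 0.08 and 1.06). The lower one was Nabp1, a single-stranded DNA-binding protein gene, at -0.68 ± 0.15 and -1.09. The other genes at least 0.5 lower on each array with the offset of 50 were Wdr78 (-0.65 ± 0.13), Edem1 (-0.51 ± 0.00), Phlda1 (-0.51 ± 0.01) and Cd8a (-0.51 ± 0.00).

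Cirbp and Rbm3, both cold-inducible RNA-binding protein genes, were higher together. Rbm3 was at 0.63 ± 0.04 with its bright probe, and its other probe was not well above background in any of the 4 channels. The complement gene C3 was at 0.53 ± 0.08 beside Cfd, while the C1q genes C1qb and C1qc were at -0.18 ± 0.15 and -0.01 ± 0.02.

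The labels give no sex for the pooled mice. Of the 9 listed sex-linked transcripts 3 were measured. Xist, expressed from the inactive X chromosome, was at 0.68 ± 0.07 with its brightest probe. Its other probes read 0.49 (0.70 and 0.28 on the arrays), 0.14 (0.25 and 0.02) and, with no channel well above background, 0.13. The Y-linked Ddx3y and Eif2s3y were at -0.13 ± 0.17 and -0.04 ± 0.33, the latter with opposite signs on the arrays. The brightest probes of Xist, Ddx3y and Eif2s3y were each well above background in 4 of 4 channels. Whether the pools differed in their share of females and males cannot be told from these values. Its part in the differences above was not tested. The Ucp1 probe, for the uncoupling protein of brown fat, was well above background in 1 of 4 channels and read 2.35 on array 1 and 0.41 on array 2.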
